A study of Mus musculus with 4 samples.

How the data were processed

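RNA was measured by sequencing in 4 libraries from the mouse uterus, collected on day 4 after mating with a vasectomized male, a procedure that makes a female pseudopregnant without embryos. Per the labels' protocols, cells of the luminal epithelium, which lines the uterine cavity, and of the underlying stroma were captured by laser microdissection, RNA was extracted with the PicoPure kit, and stranded total RNA libraries were made after ribosomal RNA depletion. Each compartment gave 1 library from a uterus labelled as a knockout of the homeobox genes Msx1 and Msx2 and 1 library from a floxed control. The series describes 1 mouse of each genotype, so genotype and animal are the same contrast, and whether both compartments came from the same mouse was not stated.

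The authors deposited 2 tables, 1 per compartment, each with 23235 genes. Per the file headers, the values are RPKM (reads scaled by transcript length in kilobases and by mapped reads), 1 column for each library, computed by the authors. The deposited log2 fold change, p-value and q-value columns are the authors' own comparison of the knockout with the control, per the file headers. Per the submitters' processing notes, CASAVA 1.8.2, TopHat, TopHat2 2.0.5, Cufflinks 2.0.2 and the mouse build mm9 were used. The role and settings of each tool, the filters and the use of strand in counting were not given in the sources used here. The columns of the tables are those of a Cufflinks comparison, in which each table is normalized within itself, so levels set across the compartments are marked as such. All columns of values belonged to a mapped library or to the authors' comparison.

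The analysis started from the RPKM as deposited. Differences were taken within a compartment as log2((knockout + 1)/(control + 1)), with a pseudocount of 1 RPKM, which understates the difference of low genes. Genes with a mean of at least 1 RPKM over the pair were kept, and a gene was counted as higher or lower when the log2 difference was at least 1 in size. With 1 library per group no test across samples was possible, no p-value was computed across genes, and the words higher and lower describe these libraries only. Ratios of single genes were taken from the RPKM without a pseudocount.

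Before the data were examined, 24 gene lists and 9 lists of cell type markers were fixed, 33 lists tried in each compartment. The median log2 difference of each list with at least 5 kept members was placed among the medians of 10000 random lists of the same size, drawn with replacement from kept genes in the same 20 bins of mean expression. A list was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile of those lists. Such percentiles describe these libraries and are not a test of the genotype. Genes were named by a rule fixed at the same time: Msx1 and Msx2; the 15 genes with the largest positive and the 15 with the largest negative log2 difference among genes reaching 5 RPKM, leaving out small RNA and unnamed gene models; up to 4 members of each list with the largest difference in size; and 20 genes with known roles in uterine receptivity. Genes named outside this rule are said to have been chosen after their values were seen.

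Depth was estimated from the values. Low RPKM values multiplied by the transcript length less 200 bp piled up at whole multiples of 1 step, taken as the value of 1 read. Lengths came from transcripts of the GENCODE vM21 annotation, matched by RefSeq identifier, and were known for 97.2% of kept genes in luminal epithelium and 96.2% in stroma. That annotation belongs to another build and was used for length and base composition only. Of the low values of each library, between 67.1% and 69.8% lay within 0.2 of a whole number of reads. Part of any evenly spread values would lie that close too, and the step was fitted to the same values. These shares are therefore no independent check of the depths. Bounds given with a ratio are 95% exact binomial (Clopper-Pearson) limits on the estimated reads. They are approximate, cover counting error only and say nothing of variation between animals, and reads made by amplification are not independent molecules.

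Coordinates are those of the deposited tables, build mm9. Starts were raised by 1, because 2812 of 20768 loci compared with the annotation had the length of a gene there when starts were counted from 0, against 458 when counted from 1. Alternatives changed 1 choice at a time, except for 2 added after the data were seen, which also left out small RNA and unnamed models while taking the mean of list members or asking for a counting interval that leaves out equal levels. The choices were the pseudocount, the scaling of the libraries, the minimum of expression, the removal of small RNA and unnamed models, the matching of random lists and the mean in place of the median. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For luminal epithelium, with 7736 genes, 6.00% of 200 random lists of 20 unshifted genes were called apart, 92.0% of lists shifted by 0.30 and 100% of lists shifted by 1.00 on the log2 scale. For stroma, with 7723 genes, the shares were 2.00%, 100% and 100%. The value of 1 read, simulated from each library over 14048 genes with transcript lengths known only roughly, was recovered with errors from -0.305% to 0.166%. Counting intervals simulated for luminal epithelium held the true ratio for 95.1% of 2000 genes. That simulation drew the reads directly, without errors of length or amplification, so it checks the calculation and not the bounds of real genes.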

Results

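The data hold gene expression in luminal epithelium and stroma captured from the mouse uterus on day 4 of pseudopregnancy, the day on which the uterus is prepared for embryo attachment. The series compared uteri labelled as knockouts of Msx1 and Msx2, homeobox transcription factors, with floxed controls, separately in each compartment. There were 4 libraries, 1 per group, so no value below has a replicate and no difference between genotypes can be set against variation between mice. The estimated depth was 6.22 M reads for the luminal epithelium control, 89.1 M for the luminal epithelium labelled knockout, 42.3 M for the stroma control and 59.8 M for the stroma labelled knockout. The luminal epithelium control was thus 14.3 times shallower than its partner, and 1 read on a transcript of 1 kb effective length stood for 0.161 RPKM there against 0.0112 RPKM. A gene listed at 0 is not read as absent, because Rpl26, a ribosomal protein gene chosen after its values were seen, was listed at 0 in both controls.

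Msx1 and Msx2 themselves were examined first, as a check of the labels. In luminal epithelium Msx1 (chromosome 5, 38211730 to 38215824, mm9) was at 23.2 RPKM in the control and 13.6 RPKM in the library labelled knockout, a ratio of 0.587 with counting limits of 0.514 and 0.671. Msx2 (chromosome 13, 53562250 to 53568149) was at 1.31 RPKM in the control and 2.06 RPKM in the library labelled knockout, which goes against the label, with a ratio of 1.58 and counting limits of 1.0 and 2.74. In stroma both genes were low, Msx1 at 0.0467 and 0.0207 RPKM and Msx2 at 0.135 and 0.0564 RPKM in control and knockout. The antisense transcript Msx1as, which shares the locus of Msx1, was at 39.0 RPKM in control luminal epithelium and 2.15 RPKM in the library labelled knockout, 18.1-fold lower. The exons deleted were not stated and the use of strand in counting was not given, so remaining Msx1 or Msx2 reads do not settle the labels and reads of Msx1 and Msx1as cannot be separated. For this reason the libraries are called labelled knockout throughout, and every direction below rests on those labels.

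The marker genes of each compartment lay where the captures should place them. General epithelial markers such as the keratins Krt8 and Krt18 and the adhesion protein Epcam had a median log2 difference, luminal epithelium against stroma, of 3.85 in the controls and 4.07 in the libraries labelled knockout. Stromal markers such as the collagens and Pdgfra had medians of -3.15 and -4.03, and endothelial markers -2.18 and -2.06. Leukocyte markers had medians of -1.34 and -1.0 and smooth muscle markers -0.62 and -1.49. Luminal epithelial markers had medians of 2.14 and 2.84, against 0.13 and 0.13 for glandular, 0.00 and 0.00 for erythrocyte and 0.03 and -0.05 for mesothelial markers. These values set levels across 2 tables that were normalized separately. Foxa2, a glandular transcription factor chosen after its values were seen, reached at most 0.0922 RPKM in any library.

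**Figure D1:**
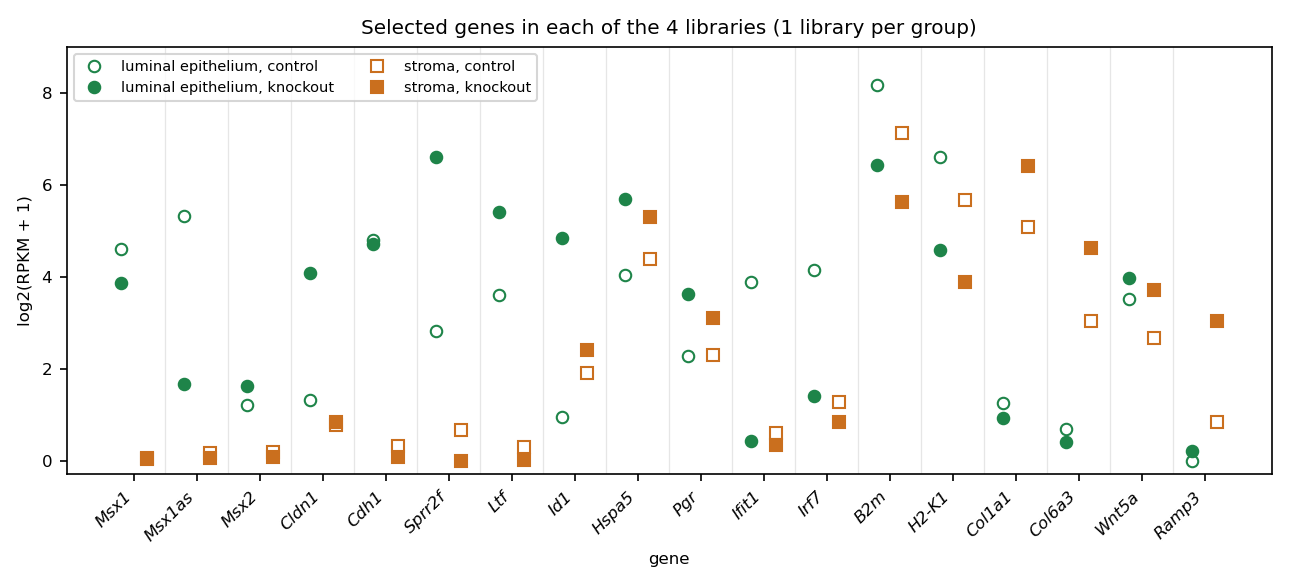
Expression of 18 genes in each of the 4 libraries, as log2(RPKM + 1) on the vertical axis, with circles for luminal epithelium, squares for stroma, open symbols for controls and filled symbols for libraries labelled knockout. Each symbol is 1 library without an error bar, and Msx1 is seen at 23.2 RPKM in control and 13.6 RPKM in labelled knockout luminal epithelium.

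The first comparison asked how luminal epithelium labelled knockout differed from control. Genes known to respond to estrogen were higher, among them Sprr2f and Sprr2g, small proline-rich proteins of the epithelial surface, and Ltf, the secreted iron-binding protein lactotransferrin. Genes of the response to protein folding stress in the endoplasmic reticulum were higher as a group, among them the chaperone Hspa5. Interferon-stimulated genes such as Ifit1, Isg15 and Irf7 were lower, and the claudin Cldn1, a tight junction protein, was 10.7-fold higher. Of 7736 genes kept, 389 were at least 2-fold higher and 154 at least 2-fold lower in the library labelled knockout. Higher genes made up 71.6% of these, and the median log2 difference of all kept genes was 0.10. Rescaling the libraries to their sums without the 50 most abundant genes moved that median by -0.19 and gave 312 higher and 232 lower, a share of 57.4%. Dividing by the upper quartile moved it by -0.13. Small RNA and unnamed models were 129 of the higher and 26 of the lower genes, and 109 of those 129 were listed at 0 in the shallow control, leaving 260 higher and 128 lower genes with names. Among named genes that rescaling without the 50 most abundant gave 188 higher and 200 lower, so the excess of higher genes depended on the scaling.

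The estrogen-responsive list had a median log2 difference of 1.82, above all 10000 random lists, with 10 of 11 kept members above 0 and 6 at least 2-fold higher. With no minimum of expression, over all 26 members in the table, the median was 0.35. Sprr2f (chromosome 3, 92169109 to 92170364) was at 6.02 RPKM in control and 95.8 RPKM in the library labelled knockout, a ratio of 15.9 with counting limits of 9.84 and 29.1. Sprr2g was at 1.67 and 55.1 RPKM. These genes belong to a family of near-identical copies among which reads can be split. Padi1 and Padi2, which convert arginine to citrulline in proteins, were at 0.963 and 8.98 RPKM and at 4.29 and 23.0 RPKM. Ltf was at 11.1 and 41.8 RPKM, a ratio of 3.76 with limits of 3.24 and 4.39. Ltf is also a glandular marker, and the other glandular marker kept, Aldh1a1, which makes retinoic acid, was at 0.789 and 4.86 RPKM. The estrogen receptor gene Esr1 was at 7.79 and 12.5 RPKM, and the cell-surface mucin Muc1 at 2.31 and 3.26 RPKM, a ratio whose counting limits of 0.986 and 2.16 reach 1.

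The progesterone-responsive list, with a median of 0.25 and 12 of 17 members above 0, lay at percentile 82.3 and did not stand apart. The progesterone receptor gene Pgr was at 3.87 RPKM in control and 11.4 RPKM in the library labelled knockout, a ratio of 2.93 with limits of 2.51 and 3.46. Irg1, an enzyme that makes itaconate, was at 36.9 and 98.6 RPKM, and the kinase Sgk1 at 17.6 and 45.4 RPKM. Ihh, the hedgehog signal sent from epithelium to stroma, was at 3.84 and 7.89 RPKM, a ratio of 2.06 with limits of 1.57 and 2.76. Areg, which encodes the growth factor amphiregulin, differed little, at 6.73 and 6.93 RPKM. The cytokine gene Lif was low, at 0.130 and 0.766 RPKM.

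The endoplasmic reticulum stress list had a median of 0.71, above all 10000 random lists, with 21 of 22 members above 0 and 5 at least 2-fold higher. Hspa5 (chromosome 2, 34627610 to 34632049) was at 15.5 RPKM in control and 50.9 RPKM in the library labelled knockout, a ratio of 3.28 with limits of 2.88 and 3.75. Xbp1, a transcription factor of this response, was at 4.89 and 15.4 RPKM. Creld2 was at 1.71 and 6.58 RPKM, and Herpud1, which takes part in disposal of misfolded proteins, at 1.32 and 4.57 RPKM.

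Among signalling genes, the Wnt list had a median of 0.52 at percentile 99.3 and the cytokine and chemokine list 0.67 at percentile 99.7. Fzd4, a Wnt receptor, was at 0.0501 RPKM in control and 5.91 RPKM in the library labelled knockout, with counting limits of the ratio from 33.2 to 991. Wnt7a was at 3.37 and 5.45 RPKM, while Wnt11 was at 14.3 and 9.46 RPKM. Nfkbia, the inhibitor of NF-kappaB, was at 13.2 and 42.3 RPKM, the colony-stimulating factor gene Csf3 at 0.836 and 4.25 RPKM and the chemokine gene Cxcl17 at 10.4 and 4.61 RPKM. The BMP, activin and TGF-beta list did not stand apart, at percentile 96.0 with a median of 0.27, though it stood apart higher under 3 of 12 alternatives, and 4 of its 18 members were at least 2-fold higher. Among these were Id1, an inhibitor of differentiation induced by BMP signals, at 0.917 and 27.8 RPKM, Id3, listed at 0 in control and at 23.1 RPKM, and Id4, at 0.687 and 6.67 RPKM. The Notch list, with a median of 0.18, and the fibroblast growth factor list, with a median of -0.10, did not stand apart, though the latter was apart lower under 1 of 12 alternatives. Etv5, a transcription factor downstream of fibroblast growth factor signals, was at 7.77 and 0.812 RPKM, 9.56-fold lower with limits of 7.91 and 11.6.

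Junction lists did not stand apart under the choices used throughout. The tight junction and polarity list had a median of 0.10 with 2 of 23 members at least 2-fold higher, both claudins. Cldn1 (chromosome 16, 26356732 to 26371925) was at 1.48 RPKM in control and 15.8 RPKM in the library labelled knockout, with limits of the ratio of 7.40 and 16.1, and Cldn23 at 10.4 and 28.1 RPKM. The adherens junction list had a median of -0.08 at percentile 3.81 and stood apart lower under 3 of 13 alternatives. Cdh1, the epithelial cadherin, was at 26.8 and 25.3 RPKM, its ratio of 0.944 having limits of 0.874 and 1.02, and Ctnnb1, which encodes beta-catenin, was at 38.6 and 33.3 RPKM. The desmosome list had a median of 0.30, with Dsp at 4.06 and 5.66 RPKM and Dsg2 at 2.85 and 3.74 RPKM. Cdsn, which encodes corneodesmosin, was listed at 0 in control and at 0.0050 RPKM. The mucin and apical surface list, with a median of -0.00, and the integrin and basement membrane list, with a median of 0.16, did not stand apart.

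The interferon-stimulated list had a median of -1.72, below all 10000 random lists, with 17 of 17 members below 0 and 13 at least 2-fold lower. Ifit1 (chromosome 19, 34715379 to 34724499) was at 13.7 RPKM in control and 0.344 RPKM in the library labelled knockout, 39.9-fold lower with limits of 30.7 and 52.9. Isg15, a ubiquitin-like modifier, was at 11.7 and 0.592 RPKM, 19.8-fold lower, and Irf7, a transcription factor of the interferon response, at 16.7 and 1.63 RPKM, 10.3-fold lower. Rtp4 was at 8.28 and 0.705 RPKM, Zbp1, a sensor of foreign nucleic acid, at 6.83 and 0.401 RPKM, and Oas2 at 6.65 and 0.231 RPKM. Leukocyte markers were lower too, with a median of -1.66 over 7 kept of 23 members (-0.19 over all 23 with no minimum of expression), 5 of them at least 2-fold lower, but 2 were above 0 and 1 of those at least 2-fold higher. Lyz2, a lysozyme of myeloid cells, was at 7.50 and 0.705 RPKM and Cd74, the class II invariant chain, at 6.36 and 0.960 RPKM. Lyz1, a second lysozyme, was at 1.48 and 6.28 RPKM and Cd14, a receptor for bacterial lipopolysaccharide, at 24.8 and 32.0 RPKM, both chosen after their values were seen. In stroma, normalized separately, Cd14 was lower, at 0.574 and 0.326 RPKM, while leukocyte markers as a list lay higher there. Cd14 thus did not behave as a leukocyte marker in these captures.

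Stromal markers were lower in the same library, with a median of -0.40 at percentile 0.225, as was the fibrillar collagen and matrix list, with a median of -0.41 at percentile 0.01 and 8 of 10 members below 0. Col3a1 was at 4.76 and 2.25 RPKM and Sparc, a collagen-binding matrix protein, at 1.84 and 0.465 RPKM, while Col5a2 was at 0.382 and 2.28 RPKM. The cell cycle list had a median of -0.23 at percentile 0.98, with 5 of 9 members below 0. Mcm6, a replication helicase subunit, was at 1.55 and 0.627 RPKM and Top2a, a topoisomerase of dividing cells, at 4.67 and 8.71 RPKM. The lists for prostaglandins (median 0.29), immediate early genes (0.25), ion and water transport (0.19), retinoids (0.01), homeobox factors (0.04), ribosomal proteins (0.19) and mitochondrial respiration (0.10) did not stand apart. Nor did general epithelial (0.10) and luminal epithelial (0.30) markers. Ptgs2, the inducible cyclooxygenase, was at 0.496 and 3.97 RPKM, a ratio of 8.0 with limits of 4.71 and 15.2, and the prostaglandin receptor gene Ptger2 at 8.44 and 2.74 RPKM.

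Of the 15 genes with the largest positive difference, Defb6 and Defb5, which encode antimicrobial defensins, were listed at 0 in control and at 59.4 and 13.9 RPKM in the library labelled knockout. Ovgp1, an oviduct glycoprotein, was at 9.24 and 89.2 RPKM, 9.65-fold higher with limits of 8.17 and 11.5, and Fabp5, a fatty acid carrier, at 1.49 and 28.8 RPKM. The difference for Lars2 rested on a failed estimate in the control. Of the 15 with the largest negative difference, Apoe, a lipid carrier, was at 8.80 and 0.499 RPKM, the glucose transporter gene Slc2a12 at 32.0 and 5.31 RPKM and the zinc finger gene Zfp248 at 6.59 and 0.0665 RPKM, 99.1-fold lower. The authors' deposited table marked 94 genes significant, 34 higher and 60 lower. The q-value there was 0.0354 for Cldn1, 3.46e-04 for Ifit1 and 9.00e-04 for Id1, but 0.190 for Irf7 and 0.921 for Hspa5, and such a test compares 2 libraries, not the genotypes. In all 9 of 27 lists stood apart, against 1.35 expected of random lists of unrelated genes. That number is no measure of chance here, because the lists hold related genes and some share members. The lists for Wnt, cytokine, cell cycle and endoplasmic reticulum stress genes did not stand apart under at least 1 alternative.

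**Figure D2:**
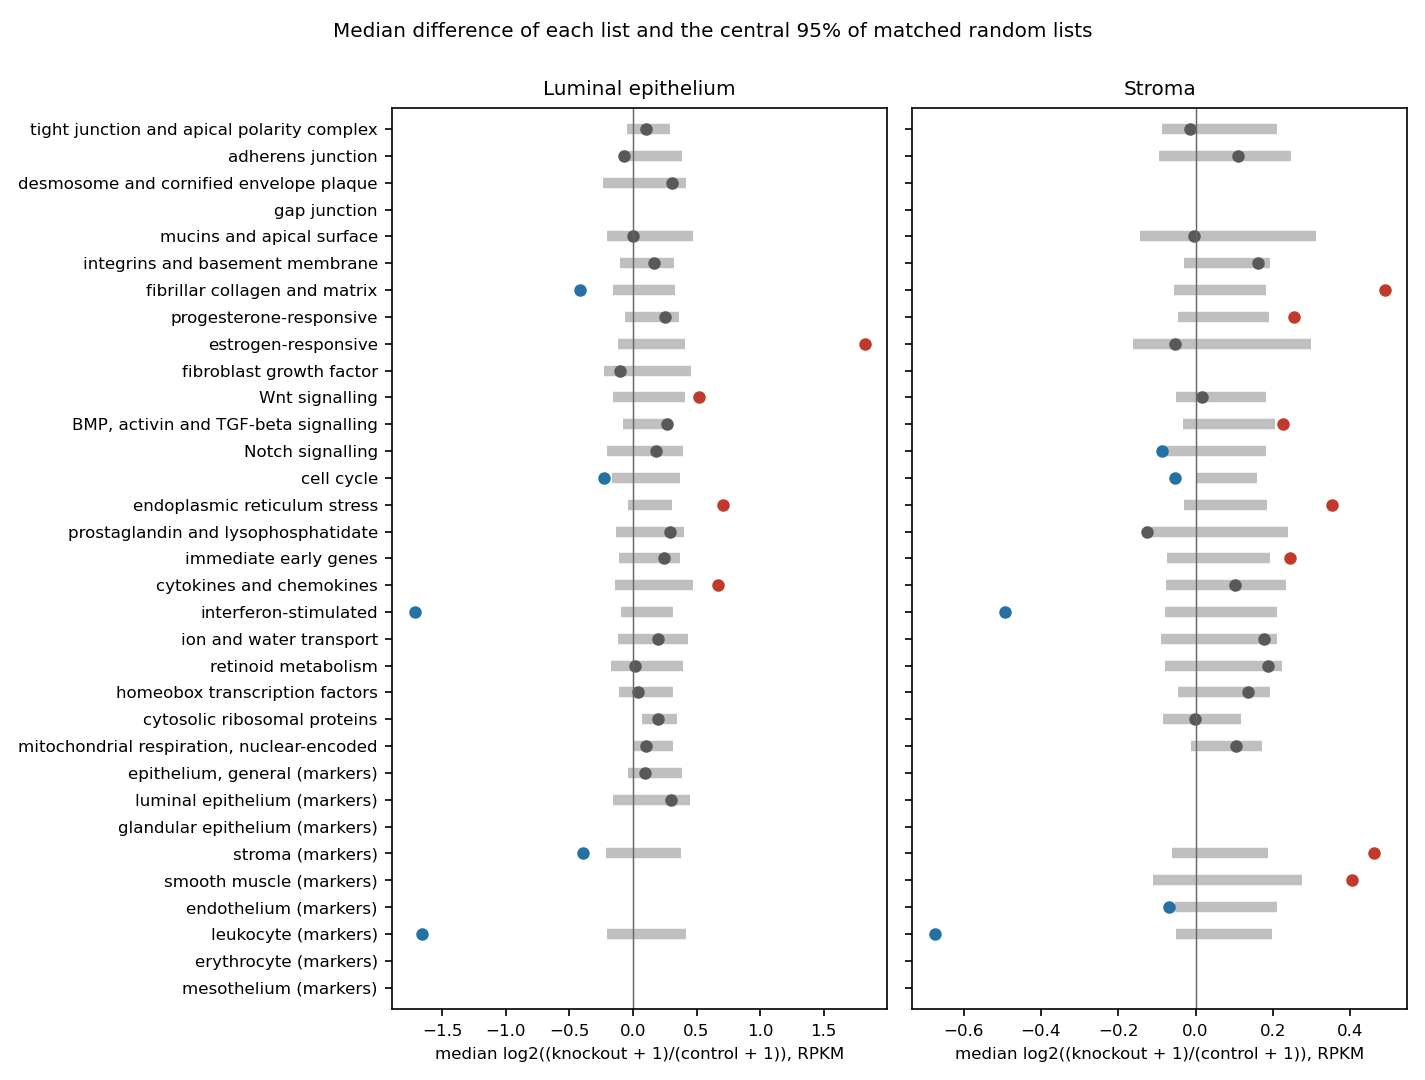
Median log2((knockout + 1)/(control + 1)) of RPKM for each gene list and marker list, in luminal epithelium on the left and stroma on the right, on horizontal axes of different range. Grey bars span the central 95% of 10000 random lists matched on expression, red and blue points are lists above and below them, grey points lie within, and lists without a point had fewer than 5 kept members. The interferon-stimulated list lies at -1.72 in luminal epithelium and -0.49 in stroma.

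The second comparison asked how stroma labelled knockout differed from control. Genes of the extracellular matrix on a fixed list were higher, among them Col6a3, Col6a2 and Col1a1, which encode chains of collagen types VI and I. H2-K1, a class I histocompatibility chain, and its partner B2m were lower. Genes of the endoplasmic reticulum stress response were higher here as well, with smaller differences than in luminal epithelium, although the contrast between compartments was not tested. Of 7723 genes kept, 112 were at least 2-fold higher and 123 at least 2-fold lower in the library labelled knockout, and the median log2 difference was 0.07. Most of these were small RNA or unnamed models, which left 34 higher and 40 lower genes with names. The spread of differences was narrower than in luminal epithelium, with 5th and 95th percentiles of -0.38 and 0.44 against -0.60 and 1.0, in libraries whose depths differed by 1.41 times.

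The fibrillar collagen and matrix list had a median of 0.49, above all 10000 random lists, with 18 of 21 members above 0 and 6 at least 2-fold higher. Col6a3 (chromosome 1, 92663435 to 92740548) was at 7.15 RPKM in control and 23.6 RPKM in the library labelled knockout, a ratio of 3.30 with counting limits of 3.16 and 3.43. Col6a2 was at 23.7 and 64.9 RPKM, Col6a1 at 29.6 and 72.2 RPKM, and Col1a1 (chromosome 11, 94797584 to 94813170) at 32.9 and 83.7 RPKM. Stromal markers, which share several collagens with that list, had a median of 0.46 above all random lists, with 16 of 20 above 0. Among stromal markers, Tcf21, a mesenchymal transcription factor, was at 0.843 and 3.78 RPKM and Hand2, a progesterone-induced transcription factor, at 4.80 and 4.57 RPKM. Smooth muscle markers had a median of 0.41 at percentile 99.8, with Tagln at 1.03 and 2.47 RPKM.

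The progesterone-responsive list had a median of 0.25 at percentile 99.8, with 11 of 16 members above 0 and none at least 2-fold higher. Pgr was at 3.88 RPKM in control and 7.62 RPKM in the library labelled knockout, Gli1, an effector of hedgehog signals, at 4.99 and 8.24 RPKM, and Fkbp4, a cochaperone of the progesterone receptor, at 6.49 and 10.8 RPKM. The endoplasmic reticulum stress list had a median of 0.35, above all random lists, with 19 of 21 members above 0 and 0 at least 2-fold higher with the pseudocount. Hspa5 was at 19.9 and 38.2 RPKM and Manf at 2.12 and 5.10 RPKM, a ratio of 2.40 without it. The BMP, activin and TGF-beta list had a median of 0.23 at percentile 99.0, with the receptor gene Bmpr1a at 2.16 and 3.28 RPKM but Id2 at 4.40 and 1.94 RPKM, and immediate early genes had a median of 0.24 at percentile 99.6. The Wnt list did not stand apart, with a median of 0.02, but Wnt5a, a ligand made by stroma, was at 5.34 and 12.1 RPKM, a ratio of 2.26 with limits of 2.11 and 2.42. Bmp2, a signal of decidualization, was low at 0.166 and 0.241 RPKM, and Hoxa10 was at 22.2 and 27.5 RPKM.

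The interferon-stimulated list had a median of -0.49, below all 10000 random lists, with 9 of 9 members below 0 but 1 at least 2-fold lower with the pseudocount. Its members Oasl2 and Rtp4 were at 1.63 and 0.707 RPKM and at 1.68 and 0.857 RPKM in control and labelled knockout. Larger differences were seen in genes outside that list. H2-K1 (chromosome 17, 34132957 to 34137278) was at 49.7 RPKM in control and 13.7 RPKM in the library labelled knockout, 3.62-fold lower, B2m at 139 and 48.5 RPKM, and the immunoproteasome subunit gene Psmb9 at 8.61 and 2.48 RPKM. Iigp1, an interferon-induced GTPase, was at 9.83 and 1.04 RPKM, 9.49-fold lower with limits of 8.08 and 11.2. Some class I histocompatibility genes are near-identical copies among which reads can be split. Leukocyte markers were lower beside them, with a median of -0.67 and 15 of 15 members below 0, including Cd74 at 52.1 and 19.8 RPKM. Ptprc, the leukocyte common antigen, chosen after its values were seen, was at 3.58 and 1.94 RPKM.

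Endothelial markers had a median of -0.07 at percentile 1.55, the Notch list -0.09 at percentile 2.10 and the cell cycle list -0.05 at percentile 0.03. Rbpj, the DNA-binding partner of Notch, was at 6.43 and 4.26 RPKM, and Cdc20, an activator of anaphase, at 5.08 and 3.72 RPKM. Among the 15 genes with the largest positive difference were Ramp3, a receptor partner for adrenomedullin, at 0.781 and 7.23 RPKM, Col6a4, a collagen type VI chain outside the fixed list, at 9.62 and 43.7 RPKM, Gas6, a ligand of the Axl receptor family, at 3.12 and 16.7 RPKM, and Dio2, which activates thyroid hormone, at 5.24 and 25.3 RPKM. The chemokine gene Cxcl14 was at 1.92 and 8.84 RPKM. Among the 15 with the largest negative difference were the chemokine gene Ccl8, at 11.6 and 2.24 RPKM, and Igfbp3, which binds insulin-like growth factors, at 7.32 and 2.04 RPKM. The authors' deposited table marked 5 stromal genes significant: Inhbb, A2m and Chst13 were higher, and Gm5779 and 4930503E14Rik lower. Inhbb, which encodes an activin subunit, was at 0.00675 and 1.34 RPKM, and these 5 were chosen after their values were seen.

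The remaining stromal lists did not stand apart, namely those for tight junctions (median -0.01), adherens junctions (0.11), mucins (-0.00), integrins and basement membrane (0.16), estrogen response (-0.05), prostaglandins (-0.13), cytokines (0.10), ion transport (0.18), retinoids (0.19), homeobox factors (0.14), ribosomal proteins (-0.00) and mitochondrial respiration (0.11). Of these, the prostaglandin list, at percentile 2.77, stood apart lower under 6 of 12 alternatives, and the estrogen, cytokine and ion transport lists stood apart under 1 each. Of 25 lists 12 stood apart, against 1.25 expected of random lists of unrelated genes, which these lists are not. Only the interferon and leukocyte lists among those 12 did so under every alternative tried. The collagen, stroma and endoplasmic reticulum stress lists, for example, lost the call only under the mean of members. They kept it under the mean when small RNA and unnamed models were also left out.

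The third comparison asked which genes differed in both compartments. The named genes lower in both included genes of antigen presentation and of the interferon response, such as B2m, H2-K1, H2-D1, Tap1, Psmb8, Psmb9, Irgm1, Iigp1 and Ifi47. Of 5460 named genes kept in both compartments, 22 were at least 2-fold lower in both, where independent lists would share 0.363, and 0 were at least 2-fold higher in both. B2m was at 289 RPKM in control and 84.7 RPKM in labelled knockout luminal epithelium, 3.41-fold lower, against 2.86-fold lower in stroma, the epithelial values being chosen after they were seen. Apoe, Lyz2, Ctss and Cd74, which are abundant in macrophages, were also among the 22. With small RNA and unnamed models included, 27 genes were higher in both, 27 lower in both and 27 opposite, of 5873 genes. Across these genes the differences had a Pearson correlation of 0.191 and a Spearman correlation of 0.133, and genes are not independent replicates. If both compartments came from 1 mouse per genotype, as the series describes 1 of each, the overlap is not evidence from separate animals.

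**Figure D3:**
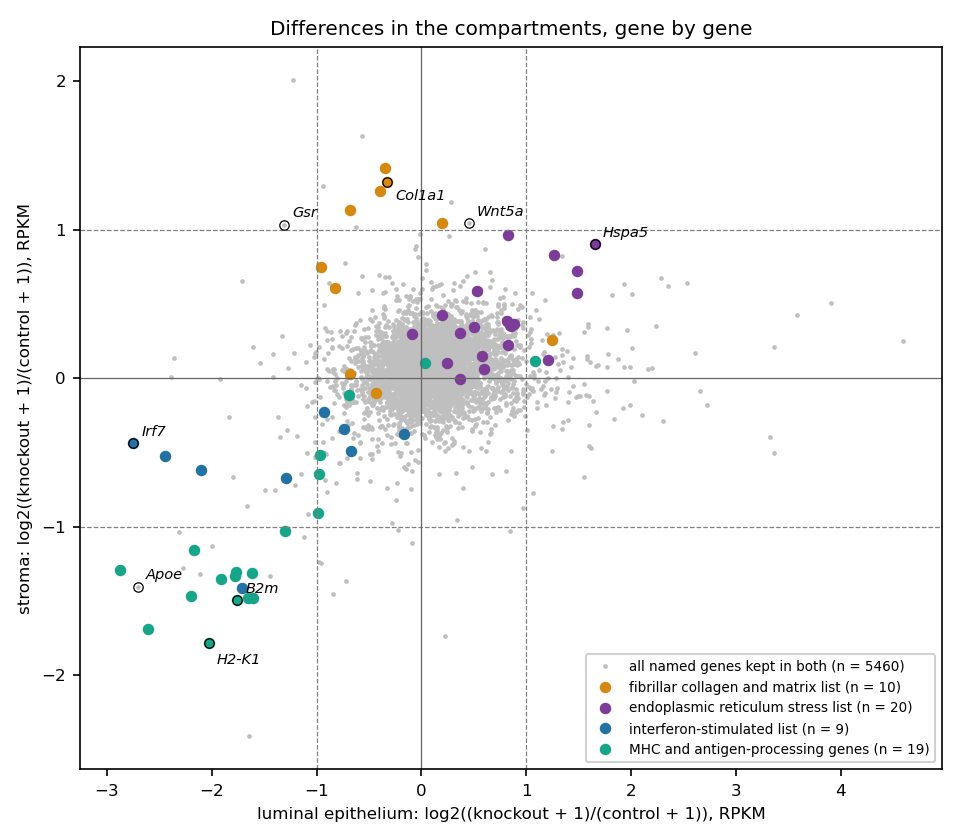
Log2((knockout + 1)/(control + 1)) of RPKM in luminal epithelium on the horizontal axis and in stroma on the vertical axis for 5460 named genes kept in both, with dashed lines at 2-fold and colours for 3 gene lists and for genes with H2 symbols or of antigen processing. B2m and H2-K1 lie in the lower left, Hspa5 in the upper right and Col1a1 above the dashed line for stroma, at 32.9 and 83.7 RPKM there.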

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

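The tests of leukocytes, of a chromosome 17 haplotype and of a larger share of stromal cells were chosen after the results they bear on were seen, as was the second test of scaling, while those of depth and base composition and the first of scaling were chosen before. Matrix genes went opposite ways in the 2 compartments, which drew attention to them. The fibrillar collagen and matrix list had a median log2 difference of -0.41 in luminal epithelium and 0.49 in stroma, and the stromal marker list, which holds several of the same collagens, had medians of -0.40 and 0.46. In luminal epithelium the stromal markers were low, with median RPKM of 0.729 in control and 0.298 in labelled knockout. In stroma, normalized separately, those medians were 13.4 and 19.1. Smooth muscle and leukocyte markers were lower too in luminal epithelium, from 0.497 to 0.0513 and from 0.529 to 0.0854. Endothelial markers, near the floor, were at 0 and 0.0140. Whether the epithelial captures held unequal amounts of carried-over stroma was not tested, so no opposite regulation is inferred. Among single genes, Gsr, a glutathione reductase, was at 13.1 RPKM in control and 4.67 RPKM in labelled knockout luminal epithelium, a log2 difference of -1.31, against 1.59 and 4.30 RPKM in stroma, a log2 difference of 1.03. Ndufs5, a subunit of respiratory complex I, was at 12.2 and 4.65 RPKM in luminal epithelium, a log2 difference of -1.23. It was listed at 0 in control stroma and at 3.02 RPKM in the stroma labelled knockout, a log2 difference of 2.01 with the pseudocount. That 0 is not read as absence, because Rpl26, of similar transcript length, was likewise listed at 0 and 3.02 RPKM there. The stromal direction of Ndufs5 is therefore uncertain. Gsr and Ndufs5 were chosen after their values were seen. The difference between compartments was not tested for any of these, since each compartment had 1 library per genotype.

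Interferon-stimulated genes as a list and many histocompatibility genes were lower in both compartments. Leukocytes carried over with the control luminal epithelium were argued against as the whole cause, provided they were like those of stroma. In the controls the interferon list lay higher in luminal epithelium than in stroma, by a median log2 of 1.75 (bootstrap interval 1.16 to 2.23). The 2 tables were normalized separately. Leukocyte markers, all 23 taken without a minimum of expression, lay lower in luminal epithelium, at -1.34. Only the 17 of 22 interferon members averaging at least 1 RPKM in luminal epithelium entered, which favours a high median. All 17 lay above 0, so the median of all 22 would lie above 0 too, though its size is not given by this test. A variant haplotype on chromosome 17 was argued against for this list, because all 13 of its members at least 2-fold lower in luminal epithelium lay on other chromosomes. In stroma a smaller number of leukocytes may account for the interferon list. Its median log2 ratio differed from that of 11 leukocyte markers by 0.0256 (interval -0.34 to 0.41). A fall of all leukocytes by the same share as those markers was argued against as the whole cause for 22 genes with H2 symbols or of antigen processing. These lay lower than those markers by a difference of -0.57 (interval -0.76 to -0.36). The interval treats genes as independent, which they are not, and an unequal fall among leukocyte types was not tested. Of them 20 were below 0, all but H2-Ke2 and H2-Ke6, which were taken in by symbol alone. Loss of a subset of leukocytes rich in antigen presentation, a haplotype acting on the histocompatibility genes themselves, an infection or immune state of 1 animal and the genotype all stay open, and with 1 animal described per genotype the last 2 cannot be separated.

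More genes were counted higher than lower in luminal epithelium labelled knockout, but 129 of the 389 higher genes were small RNA or unnamed models, 109 of them at 0 in the control, and the authors' deposited table marked 34 genes higher and 60 lower. At the deposited scaling the shallow control was argued against as the whole cause. Among named genes with a mean of at least 20 RPKM, where estimated counting error is small, 26 were 2-fold higher and 10 lower, a share of 72.2% (interval 54.8 to 85.8). That count was not repeated under another scaling, so it bears on depth only if the deposited scaling holds. Scaling was argued against by a first test, in which 64.8% of the genes 2-fold apart were higher after centring (interval 60.6 to 68.8), but that test counted the small and unnamed models and used 1 scaling. In a second test, chosen after the outcome of the first was known, named genes showed no excess when the 50 most abundant genes were left out of the scaling, with 188 higher and 200 lower, a share of 48.5% (interval 43.4 to 53.6), against 58.0% after centring and 54.5% with the upper quartile. The excess and the scaling of the libraries therefore cannot be told apart, animal, RNA quality and genotype were not tested, and these intervals treat genes as independent, which they are not.

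Collagen and matrix genes were higher in the stroma labelled knockout. Base composition was argued against, because the list stood at percentile 100 among random lists matched on expression and GC content. A larger share of stromal cells in that capture was left standing by a first test, in which stromal markers outside the matrix list differed from it by -0.31 (interval -0.77 to 0.12). A second test, chosen after the outcome of the first was known, went against it, since endothelial and leukocyte markers moved apart by 0.61 (interval 0.51 to 1.13) where a dilution would lower them alike, but leukocytes may be fewer for reasons of their own. The share of stromal cells and a regulated difference in matrix genes therefore cannot be told apart here, and animal and genotype stay confounded.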

How the results depend on the processing

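The alternatives that left out genes with a failed status, asked for a counting interval that leaves out equal levels, or took means of list members without small RNA and unnamed models were chosen after seeing the data. No called value changed sign. Of 1625 values for 325 single-gene results, 1507 kept their call, 66 lost it and 37 gained it. The other 15 were below 2-fold under both choices but changed sign. Of 651 values for 52 list results, 602 kept their call, 33 lost it and 16 gained it. In luminal epithelium the estrogen, interferon, leukocyte, stroma and collagen lists, and in stroma the interferon and leukocyte lists, stood apart under every alternative that left at least 5 members. A pseudocount of 0.1 RPKM gave 640 higher and 279 lower genes in luminal epithelium, and 5 RPKM gave 194 higher, 50 lower and 8 lower in both compartments, as a larger pseudocount shrinks the differences of low genes by construction. A minimum mean of 5 RPKM, which keeps fewer genes, gave 204 higher and 62 lower in luminal epithelium and 10 lower in both. It left 2 lists apart higher and 1 lower in luminal epithelium, and 3 higher and 1 lower in stroma, with fewer members per list. Without the 50 most abundant genes in the scaling 232 genes were lower in luminal epithelium, and the cause was not tested. Leaving out small RNA and unnamed models gave 34 higher and 40 lower in stroma, which are the named genes counted above. It gave 0 higher in both, as all 27 genes found higher in both were such models. Among named genes whose counting interval left out equal levels, 254 were higher in luminal epithelium, 33 higher and 37 lower in stroma and 0 higher in both, against 260, 34, 40 and 0 among all named genes. With no minimum 2 lists were apart higher in luminal epithelium, and the cause was not tested. The mean of members gave 2 lists apart higher in luminal epithelium, 0 higher in stroma and 2 lower in stroma. Those higher in luminal epithelium were the estrogen list and the BMP, activin and TGF-beta list, which by its median did not stand apart. With small RNA and unnamed models also left out the mean gave 7 higher, not the same 7 lists as the median, and 3 lower in stroma, and the cause was not tested. Summing repeated symbols moved nothing, as no symbol was repeated. The luminal epithelium control limits what can be seen of low genes there, and being the sole library of its group it could not be left out. No paired analysis was possible because each group held 1 library and groups shared fewer than 2 replicate numbers.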

Other observations

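Six3, a homeobox transcription factor chosen after its values were seen, was at 4.53 RPKM in control and 0.0237 RPKM in labelled knockout luminal epithelium, 191-fold lower with counting limits of 93.7 and 512. Lifr, the receptor for leukemia inhibitory factor, was at 1.68 and 6.18 RPKM in luminal epithelium. Rdx, which links the apical membrane to actin, was at 75.5 and 40.0 RPKM there. Gm5779, an unnamed model also chosen after its values were seen, was lower in both compartments, at 4.31 and 0.00350 RPKM in luminal epithelium and 7.17 and 0.0275 RPKM in stroma.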
